A study of Homo sapiens with 9 samples.

How the data were processed

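Messenger RNA was sequenced from 9 libraries of 16D cells, a castration-resistant prostate cancer line, in 3 groups of 3. All cells carried a CRISPR knockout of OGDHL, a paralog of the E1 subunit of the mitochondrial 2-oxoglutarate dehydrogenase complex. Per the labels they had adapted for 6 weeks to the antiandrogen enzalutamide, were transduced with eGFP, with knockout-resistant full-length OGDHL or with a knockout-resistant form lacking its mitochondrial targeting sequence (dMTS), and were kept at 10 µM enzalutamide. Every column of the table was matched to a sample by its title. Libraries were made with a stranded kit that enriches mRNA and primes at random, and were read as pairs of 50 bases on a NovaSeq X Plus.

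The authors deposited a table of transcripts per 1000000 (TPM) with 36650 genes, of which 9835 have no symbol and 94 were at 0 in every library. STAR and GRCh38 are named in the submitters' notes without a version. The quantifier and the annotation release are not given in the sources used here. Each column summed to 1000000. The length column equalled the genomic span of the gene, introns included. For values under 20 reads, TPM times this length fell within 0.01 of a whole multiple of 1 step per library in 71.7% to 74.3% of cases, so the deposited TPM were divided by genomic span rather than transcript length. The level of a gene with long introns is therefore understated, and levels of different genes are not comparable as transcript numbers. The steps give an estimated depth of 86.3 M reads (M, 1000000) in eGFP replicate 3 to 121 M in dMTS replicate 2. These are estimates, so no counting interval or floor is given. The 37 mitochondrially encoded genes, which have no introns, took 54.9% to 66.0% of TPM but 14.8% to 22.5% of estimated reads.

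Genes with a TPM of at least 1 in at least 3 of the 9 libraries were tested, 13231 genes or 36.1% of the table, among them 8858 protein-coding genes. The span-based TPM make this filter remove many genes with long introns. The test was a linear model in limma 3.58.1 (R 4.3.3, data.table package, version 1.17.8) on log2(TPM + 1), with the variance trend of eBayes, all 9 libraries, 6 residual degrees of freedom and no covariate. Log2 fold changes from this model are differences of log2(TPM + 1). At low TPM they are therefore smaller in size than the ratio of the TPM levels. With span-based TPM this also affects genes that have long introns but many reads. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a call at an adjusted p under 0.05. The reported calls use no model of counts, since the table holds TPM. Every count is given as deposited, and again with each library rescaled so that the median log2 ratio of the tested genes to their means was 0. The median ratios that this removed ran from -0.13 in eGFP replicate 3 to 0.28 in dMTS replicate 2.

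Before the data were examined, 25 gene lists, the named-gene rule, the comparisons and the first set of alternatives were fixed. Lists with at least 5 tested members were tested by camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with the correlation estimated per list and fry, which tests whether a list moves on balance in one direction, were alternatives. Named genes were OGDHL, its complex partners and relatives, and a set of androgen-responsive, neuroendocrine and proliferation markers; some of the named genes are not reported here. To these were added, per comparison and scaling, up to 8 called genes in each direction with the largest fold change, a symbol, no overlap between the groups' libraries and a mean of at least 1 TPM in the higher group. The last part was the top members of the lists, 4 where a list was called and fewer otherwise. Single TPM values of OGDHL were compared by an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1.

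The alternatives fixed beforehand were a pseudocount of 0.1 or 5, no filter, a mean TPM of at least 5, rescaling, TPM recomputed without OGDHL and the mitochondrially encoded genes, the replicate number as a block, only the 6 libraries compared, a robust eBayes, a log2 fold minimum of 1 and leaving out each library in turn. Added after seeing the data were limma-voom on the estimated reads (at least 10 reads in at least 3 libraries) with and without rescaling, rescaling combined with the block, with array weights, with each library left out or with OGDHL not among the genes adjusted over, TPM recomputed without the mitochondrially encoded genes alone, and the lists rescaled without dMTS replicate 2. A list direction or gene was taken to reverse only if it was called before or after the change. The overlap of comparisons that share a group was set beside 100 simulated data sets with unchanged groups, and the covariance of fold changes, corrected for the noise of the eGFP means, beside all 840 regroupings of the libraries. The eGFP libraries were also divided between the comparisons in all 6 ways.

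The tests were also run on simulated data built on these libraries with 200 changed genes per comparison. At a log2 change of 1, 94.0% to 100% of the changed genes were recovered as deposited and 92.5% to 98.5% rescaled. At a log2 change of 0.5 the recovery was 46.3% to 70.1% as deposited and 86.6% to 91.0% rescaled. Beside the 200 changed genes, 10 to 16 unchanged genes were called as deposited and 5 to 12 rescaled. A 20-gene list shifted by 0.3 was called in every case, and of 20 or 21 unchanged lists 1 was called in 1 of the settings and none in the others. The simulated genes varied independently, and the changed ones were drawn from the better expressed of the tested genes. The simulation therefore does not show how often camera calls an unchanged list whose members vary together. Other splits of the real libraries called up to 9 lists. Between libraries of a group the correlation of log2 values across genes was 0.990 to 0.997, and 0.985 to 0.996 between groups. Figures and summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.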

Results

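The data are mRNA levels in 9 libraries of OGDHL-knockout 16D prostate cancer cells that had adapted to enzalutamide, 3 with eGFP, 3 with full-length OGDHL and 3 with the dMTS form. The estimated depth was 86.3 to 121 M reads (M, 1000000) per library. The series holds no cells without the knockout. The comparisons therefore set knockout cells given each form of OGDHL against knockout cells given eGFP. Whether the cells of the groups also differ in other ways is not known. No label says whether the replicates of a group were separate cultures, so the p-values measure only the spread between these samples. The dMTS libraries differed most among themselves. In dMTS replicate 2 the mitochondrially encoded genes took 54.9% of TPM, against 61.2% ± 5.59 (SD, n = 3) over its group and 63.9% ± 1.96 (SD, n = 3) with eGFP. MALAT1, a nuclear long noncoding RNA, was at 816 and 878 TPM in dMTS replicates 2 and 3 and at 1151 to 1374 TPM in the other libraries. The log2 values of dMTS replicate 1 correlated across genes at 0.990 and 0.994 with dMTS replicates 2 and 3 and at 0.996 with full-length replicate 2.

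OGDHL mRNA was far higher in both rescue groups than with eGFP. Without unedited cells, whether it was restored to its usual level or exceeded it is not known. Its level was 1.19 ± 0.07 TPM (SD, n = 3) with eGFP, 218 ± 52.8 TPM with the full-length form and 125 ± 49.5 TPM with the dMTS form. The gene (ENSG00000197444) lies on the minus strand of chromosome 10 from 49734641 to 49762379 in GRCh38. Against eGFP the log2 fold change of TPM + 1 was 6.62 (SE 0.25, limma Benjamini-Hochberg adjusted p = 2.38e-07) for full-length and 5.77 (SE 0.25, adjusted p = 1.09e-06) for dMTS. The added 1 makes both values smaller than the ratio of the TPM levels. All 3 libraries of each form lay above all 3 eGFP libraries. The difference between the forms, 0.85 (SE 0.25), did not pass the limma test (adjusted p = 0.517, or 0.182 rescaled). The exact permutation p was 0.1 for each form against eGFP, the smallest that 3 against 3 libraries allow, and 0.2 between the forms. The table gives gene totals, so the residual level with eGFP does not show whether the edited transcript encodes a protein.

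**Figure D1:**
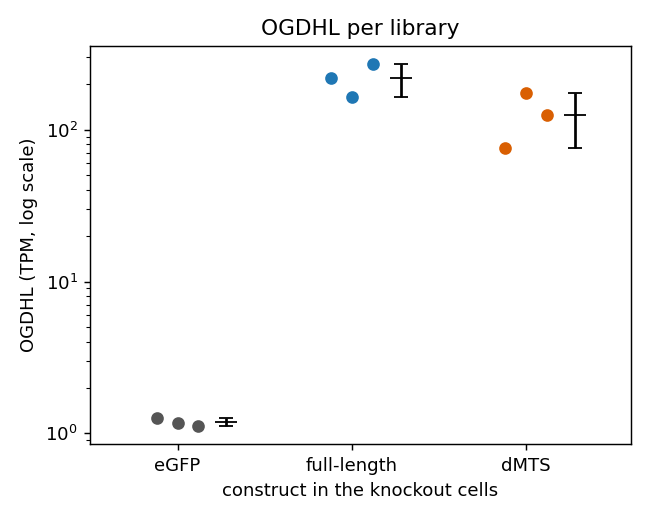
OGDHL in TPM on a log axis, by construct; each point is 1 library and the bar beside it is the mean ± SD (n = 3). The eGFP libraries lie between 1.12 and 1.26 TPM, the full-length libraries between 165 and 270.5 TPM and the dMTS libraries between 76.1 and 175 TPM.

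Androgen-responsive genes and neuroendocrine markers were set side by side, since the cells grew under enzalutamide. KLK3, which encodes prostate-specific antigen, was at 1179 ± 25.5, 1108 ± 8.01 and 1124 ± 99.8 TPM (SD, n = 3 each) with eGFP, full-length and dMTS. The mean levels of TMPRSS2 (14.7, 14.2 and 16.2 TPM), FKBP5 (2.29, 2.45 and 2.47), ENO2 (8.73, 8.23 and 9.74) and the proliferation marker MKI67 (24.4, 26.0 and 29.0) are given in that order too. The partners and relatives of OGDHL were at 7.51, 7.62 and 8.72 TPM for OGDH, 3.28, 3.33 and 3.69 for DHTKD1, 14.8, 14.8 and 15.9 for DLST, and 14.1, 14.7 and 16.0 for DLD. None of these 9 genes was called by limma in any comparison, as deposited or rescaled. CHGA and SYP did not reach the level tested, with highest library values of 0.0210 and 0.718 TPM. The list of androgen-responsive genes (27 tested) and the neuroendocrine list (5 tested) were not called in any comparison, with camera adjusted p of 0.967 and 0.839 for full-length and 0.912 and 0.188 for dMTS against eGFP.

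Full-length OGDHL left few single genes past the test against eGFP. As deposited, limma called 1 gene, OGDHL itself, with 261 genes (1.97%) at an unadjusted p under 0.05. After rescaling 4 genes were called. OGDHL and RPPH1, the RNA component of RNase P, rose, while CDKN1A, the cell cycle inhibitor p21, and the long noncoding RNA LINC00161 fell. LINC00161 is named because the count is small, having been chosen after its values were seen. RPPH1 went from 4.18 ± 0.249 to 7.71 ± 0.657 TPM (SD, n = 3; rescaled log2 fold change 0.74, SE 0.08, adjusted p 0.0426), and CDKN1A from 52.2 ± 1.95 to 40.5 ± 1.85 TPM (rescaled -0.37, SE 0.04, adjusted p 0.0426). RPPH1 is not polyadenylated, so its yield in such libraries can vary. The 3 genes besides OGDHL passed only with OGDHL among the genes adjusted over; without it their adjusted p was 0.0568. As deposited 2 genes were called without full-length replicate 2 or dMTS replicate 1. The rescaled count was 13 without dMTS replicate 1, 2 without full-length replicate 2 or dMTS replicate 3 and 1 without any other library. Voom called 6 genes, or 5 rescaled. The groups' libraries did not overlap for 11.5% of genes as deposited and 17.7% rescaled. The mean over all 10 splits of the 6 libraries is 10%. Genes that vary together can put a given split far from that mean, and this spread was not measured.

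By gene list, small shifts against eGFP passed camera for 5 lists with full-length OGDHL. The endoplasmic reticulum unfolded protein response, the chaperones and folding enzymes of the secretory pathway, was higher (median log2 fold change 0.12 over 20 genes, adjusted p = 6.21e-05), with HSP90B1 at 0.22 and PDIA4 at 0.17. The p53 targets were lower (-0.06 over 19 genes, adjusted p = 0.00483), with CDKN1A at -0.36 and BAX at -0.15. Cell cycle genes were higher (0.06 over 38 genes, adjusted p = 0.0213), as were cholesterol synthesis genes (0.06 over 23 genes, adjusted p = 0.0231), and nuclear-encoded oxidative phosphorylation was lower (-0.04 over 72 genes, adjusted p = 0.0439). No member of these 5 lists was called as deposited, over all genes or adjusted over the list alone. After rescaling, CDKN1A was called over all genes, and adjusted over the list alone 4 unfolded protein response genes were higher and 2 p53 targets lower. Every list lost its call as deposited with an estimated correlation (adjusted p = 0.993) and with fry (0.978), and after rescaling the unfolded protein response and the p53 targets had an adjusted p = 0.129 with an estimated correlation and 0.0121 with fry. Rescaling added the integrated stress response (camera adjusted p = 0.00999), nucleotide synthesis (0.0280), MYC targets and ribosome biogenesis (0.0280) and fatty acid metabolism (0.0438), with an adjusted p of 0.461 to 0.739 with an estimated correlation. The cell cycle call was lost without eGFP replicate 3 (0.237) or full-length replicate 1 (0.0809), and the cholesterol call without eGFP replicate 1 (0.0596) or full-length replicate 3 (0.170). The oxidative phosphorylation call was lost without eGFP replicate 3 (0.310), full-length replicate 1 (0.359), full-length replicate 3 (0.561) or dMTS replicate 3 (0.0593). Calls were gained for the mitochondrially encoded mRNAs without eGFP replicate 3 (0.00361), the integrated stress response without full-length replicate 3 (0.0418) or dMTS replicate 2 (0.0264), and fatty acid metabolism without full-length replicate 2 (0.0267) or dMTS replicate 1 (0.0216).

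More genes were called for dMTS against eGFP, most of them lower with dMTS. IGFBP3, a secreted binding protein of insulin-like growth factors, fell from 82.7 ± 9.05 to 25.1 ± 5.05 TPM (SD, n = 3; log2 fold change -1.69, SE 0.13, limma Benjamini-Hochberg adjusted p = 0.000373). SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, fell from 5.12 ± 0.587 to 1.81 ± 0.284 TPM (log2 fold change of TPM + 1 -1.12, SE 0.10, limma adjusted p = 0.00104). At these levels the added 1 makes the fold change smaller in size than the ratio of the TPM. The dominant-negative helix-loop-helix factors ID1 (-0.97, adjusted p = 0.0175) and ID3 (-0.86, adjusted p = 0.0102) fell from 99.8 to 51.2 and from 147 to 81.3 TPM. The phosphatase gene DUSP2 (-0.80, adjusted p = 0.0102), the disulfide isomerase AGR2 (-0.77, 0.00942), the neuropeptide gene CARTPT (-0.74, 0.0443) and the alanine aminotransferase GPT (-0.57, 0.0443) also fell. AGR2 was at 1.89 TPM with eGFP. Because TPM were divided by genomic span, that value does not show how many reads it had.

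Fewer genes rose with dMTS OGDHL as deposited. INSIG1, a sterol-regulated brake on cholesterol synthesis, rose from 39.1 ± 2.81 to 69.2 ± 14.1 TPM (SD, n = 3; log2 fold change 0.79, SE 0.14, adjusted p = 0.0443). GPX8, a peroxidase of the endoplasmic reticulum, rose from 3.96 ± 0.239 to 6.73 ± 1.29 TPM (0.63, SE 0.11, adjusted p = 0.0443). TP53TG3B (0.67, adjusted p = 0.0443) belongs to a family of near-identical copies and MRPS18AP1 (-0.72, adjusted p = 0.0102) is a pseudogene, so reads of either cannot be placed with certainty. After rescaling, the stearoyl-CoA desaturase SCD (0.81, adjusted p = 0.0103), the stress-induced cytokine GDF15 (0.74, 0.0359), the helix-loop-helix factor HES6 (0.63, 0.0152) and the acyl-CoA synthetase ACSL1 (0.63, 0.0149) rose as well; as deposited their adjusted p was 0.0523, 0.0915, 0.0569 and 0.0979. The U6 gene RNU6-9 (1.86, 0.0398) was near 0 with eGFP at 0.112 TPM, and RAB11FIP1P1 (-0.86, 0.0420) is a pseudogene.

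**Figure D2:**
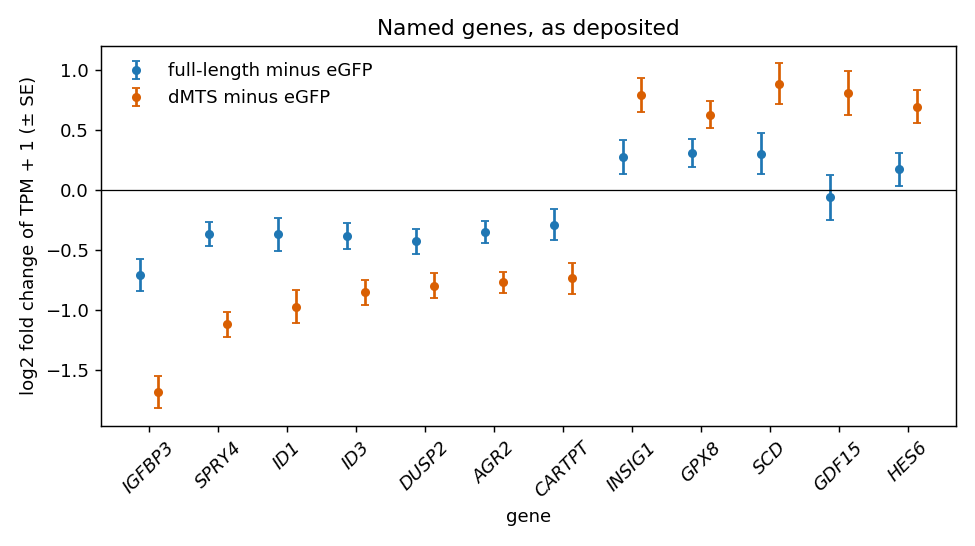
Log2 fold change of TPM + 1 against eGFP, as deposited, for 12 named genes; points are limma estimates and bars their SE (3 libraries per group). IGFBP3 lies at -1.69 with dMTS and -0.71 with full-length OGDHL, and INSIG1 at 0.79 and 0.27; none of the full-length values passed the test.

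In all, limma called 68 genes as deposited for dMTS against eGFP, 7 higher and 61 lower, with 1446 genes (10.9%) at an unadjusted p under 0.05. After rescaling it called 1240, 439 higher and 801 lower, so 10.3% of the calls were higher as deposited and 35.4% rescaled. All 68 were among the 1240 with the same sign. The groups' libraries did not overlap for 11.8% of genes as deposited and 32.4% rescaled. The mean over all 10 splits of the 6 libraries is 10%, and the spread between splits was not measured. The count of 68 fell to 3 without eGFP replicate 2 and rose to 467 without dMTS replicate 1; the other values are 4 and 10 without eGFP replicates 1 and 3, 16, 35 and 37 without full-length replicates 1, 2 and 3, and 85 and 8 without dMTS replicates 2 and 3. The rescaled count fell to 60 without eGFP replicate 2, 97 without dMTS replicate 3, 176 without dMTS replicate 2, 209 without eGFP replicate 3, 558 without eGFP replicate 1 and 562, 892 and 851 without full-length replicates 1, 2 and 3, and rose to 2360 without dMTS replicate 1.

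Many genes of protein folding and amino acid stress were called higher with dMTS OGDHL after rescaling, but none as deposited over all genes. In the endoplasmic reticulum unfolded protein response list 13 of 20 tested genes rose after rescaling and none fell, among them the chaperones HSP90B1 (0.40, adjusted p = 0.00616) and HSPA5 (0.26, 0.0103), the disulfide isomerase PDIA4 (0.31, 0.00398) and the secreted factor MANF (0.31, 0.0130). As deposited 0 of the 20 were called by limma over all genes and 7 when adjusted over the list alone (15 rescaled); the median log2 fold change was 0.29, or 0.23 rescaled, and camera gave an adjusted p = 3.01e-08. In the ATF4 and integrated stress response list 11 of 23 rose after rescaling and none fell, with the serine synthesis enzyme PSAT1 (0.34, 0.00295), the asparagine synthetase ASNS (0.23, 0.00833), MTHFD2 of mitochondrial folate metabolism (0.30, 0.00590) and the mTORC1 inhibitor DDIT4 (0.33, 0.0142). As deposited 0 of these 23 were called over all genes and 9 when adjusted over the list alone (15 rescaled), with a median of 0.26, or 0.19 rescaled, and a camera adjusted p = 7.77e-07. Both lists lost the call as deposited with an estimated correlation (adjusted p = 0.980) and with fry (0.593), and after rescaling the adjusted p was 0.125 and 0.178 with an estimated correlation, while fry gave 0.000305 and 0.00112.

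Part of the lipid synthesis genes were called higher after rescaling. In the cholesterol list 11 of 23 rose after rescaling and 1 fell, with INSIG1, the demethylases MSMO1 (0.35, adjusted p = 0.00748) and CYP51A1 (0.32, 0.00833), and the sterol carrier STARD4 (0.48, 0.0235). As deposited 1 was called over all genes and 7 when adjusted over the list alone (median 0.23, or 0.17 rescaled; camera adjusted p = 1.06e-05). In the fatty acid list 7 of 20 rose after rescaling and 1 fell, with SCD, the desaturase FADS2 (0.50, 0.00702), ACSL1 and ACSL3 (0.34, 0.0103). As deposited 0 were called by limma over all genes and 5 when adjusted over the list alone (median 0.16, or 0.11 rescaled; camera adjusted p = 0.000220). The adjusted p was 0.980 with an estimated correlation as deposited, and after rescaling 0.210 for cholesterol and 0.253 for fatty acids with an estimated correlation. Fry gave an adjusted p of 0.593 for both as deposited, and 0.00159 and 0.00598 after rescaling.

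Lists of energy metabolism also passed camera, and with all 9 libraries the nuclear and mitochondrial genomes differed in direction. Glycolysis genes were higher (median 0.15, or 0.08 rescaled; camera adjusted p = 0.000846), and after rescaling 4 of 19 rose, among them LDHA (0.27, adjusted p = 0.0470), PFKP (0.17, 0.0246) and HK2 (0.22, 0.0300). Nuclear-encoded oxidative phosphorylation was higher (0.11, or 0.04 rescaled; adjusted p = 0.00501), and after rescaling 2 of 72 rose, NDUFA5 of complex I (0.24, 0.00849) and cytochrome c, CYCS (0.24, 0.0152). The TCA cycle list was higher (0.11, or 0.05 rescaled, camera adjusted p = 0.0184). After rescaling 1 of its 24 tested genes rose, PCK2 (0.20, limma adjusted p = 0.0291), which is also in the integrated stress response list. The hypoxia list was higher too (0.21, or 0.15 rescaled, camera adjusted p = 0.0184), with 2 of 14 rising after rescaling, ERO1A (0.19, 0.0195) and MXI1 (0.18, 0.0265). No gene of these 4 lists was called as deposited, over all genes or adjusted over the list alone. The 13 mitochondrially encoded mRNAs were lower (-0.08, or -0.15 rescaled; camera adjusted p = 0.000993, or 0.140 rescaled), with MT-ND4L at -0.24 and MT-ND5 at -0.24, and none was called. That decrease rested on dMTS replicate 2: without it the direction turned and the adjusted p was 0.767, and without eGFP replicate 3 the adjusted p was 0.121. The hypoxia call was lost without dMTS replicate 3 (0.0633). All 5 lists had an adjusted p of 0.980 with an estimated correlation, and after rescaling 0.217 to 0.818 with an estimated correlation. Fry gave an adjusted p of 0.593 to 0.612 as deposited. After rescaling fry gave 0.00598 for the TCA cycle, 0.0262 for hypoxia and 0.0408 for glycolysis. It gave 0.481 for oxidative phosphorylation and for the mitochondrially encoded mRNAs.

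Further lists moved little as a whole. Rescaling brought cell cycle (adjusted p = 0.0355, CCNB1 0.19), nucleotide synthesis (0.0411, RRM1 0.17) and p53 targets (0.0290, CDKN1A -0.24) past camera, with an adjusted p of 0.493, 0.399 and 0.245 with an estimated correlation. Fry after rescaling gave 0.0917, 0.0127 and 0.0101. The p53 median was 0.02 as deposited and -0.04 rescaled, so its sign depends on the scaling. As deposited the cell cycle and nucleotide lists were not called (0.0837 and 0.0776), except without dMTS replicate 3 (0.0208 and 0.0477). Among luminal epithelial markers, which as a list were not called (adjusted p = 0.759), 2 of 14 rose after rescaling and 4 fell, with EPCAM at 0.21 and the transcription factor GATA2 at -0.39; the list's median was 0.09 while its test pointed down. Of the androgen-responsive genes 3 of 27 rose after rescaling and 3 fell, with PMEPA1 at -0.29. Not called by camera either as deposited or rescaled were MYC targets (0.188, MYC rose after rescaling, 0.19), mitochondrial chaperones (0.397, HSPD1 0.15 and HSPA9 0.14 rose after rescaling), glutamine and aspartate metabolism (0.585), homologous recombination (0.727, RPA3 0.15), type I interferon (0.633, STAT2 -0.18) and the 2-oxoglutarate-dependent dioxygenases (0.801, the demethylase KDM6B fell after rescaling, -0.25). Of these, fry after rescaling called the mitochondrial chaperones (adjusted p 0.0168) and glutamine and aspartate metabolism (0.0141). The interferon median was 0.07 while its test pointed down. No basal or immune gene reached the level tested, the highest group mean of each list being 0.494 TPM for ITGB4 with dMTS and 0.442 TPM for CD68 with full-length OGDHL. Because TPM were divided by genomic span, this does not show that every such gene was silent. The basal gene ITGA6 had a mean of 3621 estimated reads per library, while the immune genes had at most 34.8 (CD68). Of 4 mesenchymal genes tested none was called over all genes and 2 were lower when adjusted over the list alone, and of 4 inflammatory genes NFKBIA fell after rescaling (-0.35, adjusted p = 0.0420).

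**Figure D3:**
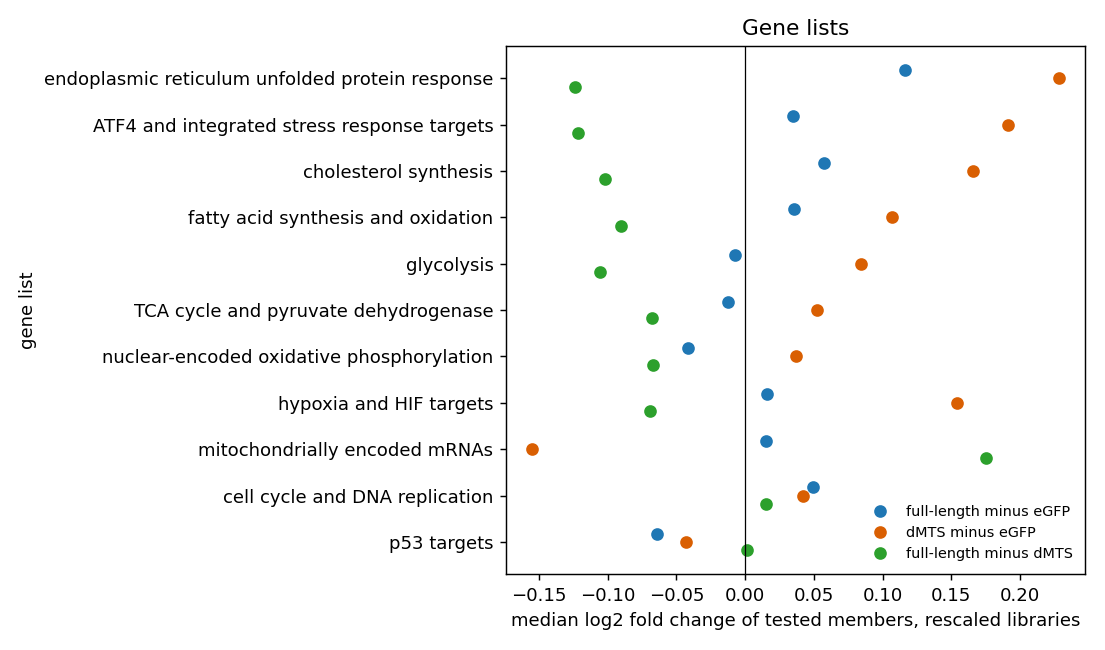
Median log2 fold change of the tested members of 11 lists after rescaling, in 3 comparisons (3 libraries per group); each point is 1 list and no spread is drawn. The unfolded protein response lies at 0.23 for dMTS and 0.12 for full-length OGDHL against eGFP, and at -0.12 for full-length minus dMTS; the mitochondrially encoded mRNAs turned direction without dMTS replicate 2.

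The direct comparison of the OGDHL forms asked which changes depend on the mitochondrial targeting sequence. Several metabolic lists were lower with full-length than with dMTS OGDHL, though no single gene passed the test as deposited. Nuclear-encoded oxidative phosphorylation had a median log2 difference of -0.13 (-0.07 rescaled, 72 genes, camera adjusted p = 4.41e-08), with COX7C at -0.19. The integrated stress response had -0.17 (-0.12 rescaled, adjusted p = 2.61e-07), with GDF15 at -0.87 and DDIT4 at -0.39, and the unfolded protein response had -0.19 (-0.12 rescaled, adjusted p = 1.23e-05), with MANF at -0.26. Cholesterol synthesis (-0.16, adjusted p = 2.12e-05; INSIG1 -0.52), glycolysis (-0.17, 2.24e-05; ALDOC -0.50), fatty acid metabolism (-0.14, 0.000213; SCD -0.58), the TCA cycle (-0.13, 0.00136; PCK2 -0.28) and hypoxia targets (-0.11, 0.0302; BNIP3 -0.37) were lower too. PCK2 is also a member of the integrated stress response list. The mitochondrially encoded mRNAs were higher with full-length (0.11, or 0.18 rescaled; adjusted p = 8.12e-07), but without dMTS replicate 2 the direction turned and the adjusted p was 0.983. All 9 lists lost the call as deposited with an estimated correlation (adjusted p = 0.951) and with fry (0.587), and after rescaling the smallest adjusted p with an estimated correlation was 0.0695. After rescaling fry gave 0.00376 for the TCA cycle, the integrated stress response and the unfolded protein response. It gave 0.00932 for cholesterol synthesis, 0.0243 for fatty acid metabolism and 0.0533 to 0.525 for the rest. Rescaling added glutamine and aspartate metabolism (-0.04, camera adjusted p = 0.0309, 0.154 with an estimated correlation and 0.00932 with fry). Fry after rescaling also called the mitochondrial chaperones (0.0132), which camera did not.

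Limma called 0 genes between the forms as deposited, with 717 (5.42%) at an unadjusted p under 0.05. It called 1 after rescaling, an unnamed long noncoding RNA (ENSG00000289913) that was higher with full-length (0.44, adjusted p = 0.0343) and that was singled out after its values were seen. Voom called 9, or 14 rescaled. Adjusted over the list alone, 1 integrated stress response gene was lower as deposited and 10 after rescaling, as were 10 of the unfolded protein response, 7 of cholesterol synthesis and 4 of fatty acid metabolism after rescaling. Other lists held calls both ways after rescaling, with 1 gene higher and 5 lower for glutamine and aspartate metabolism (1 higher as deposited), 4 higher and 1 lower for the androgen-responsive genes, and 3 higher and 4 lower for the luminal markers. The TCA cycle, nucleotide and neuroendocrine lists had 1 lower each, and the dioxygenases 1 higher. The groups' libraries did not overlap for 8.92% of genes as deposited and 17.4% rescaled. The mean over all 10 splits of the 6 libraries is 10%, and the spread between splits was not measured. Without dMTS replicate 1 the count was 58 as deposited and 911 rescaled, and without any other library 0 both ways. The hypoxia call was lost without full-length replicate 2 (adjusted p = 0.135), dMTS replicate 2 (0.0542) or dMTS replicate 3 (0.160).

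The fold changes of both forms against eGFP were correlated across genes. OGDHL was the 1 gene called in both comparisons as deposited, and OGDHL, RPPH1, CDKN1A and LINC00161 were the 4 after rescaling, all with the same sign. Among the 67 other genes called for dMTS, 65 had a full-length value of the same sign, and after rescaling 1208 of 1239. These genes were chosen for their dMTS values against the same eGFP libraries, which favours a shared sign and a smaller full-length value. Across the 13231 genes, which are not independent replicates, the correlation of both sets of fold changes was 0.66, against a mean of 0.50 in 100 simulated data sets with unchanged groups and the same shared controls, in which genes varied independently. The rescaled covariance was 0.0129, against a simulated mean of 0.00556. With the 3 eGFP libraries divided as 1 and 2 between the comparisons, the rescaled correlation was 0.25 to 0.40 over the 6 divisions. No library was shared there, so this part of the correlation does not come from a library counted in both comparisons. It does not establish a shared effect, since what all eGFP libraries have in common stays in every division. Of the 840 regroupings of the 9 libraries, 49, the real one among them, gave a covariance, corrected for the shared controls, as large as the real one. The regroupings keep the correlation between genes, and the real one did not stand out among them, so chance is not excluded. The real groups with dMTS as the common group are only 1 of the 840. Regroupings that keep the real groups in part carry their differences too, so the share is not an exact p. No gene was called for full-length against both other groups in limma, as deposited or rescaled.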

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

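The voom fits, the array weights, the rescaled counts with a block, with a library left out or adjusted without OGDHL, and TPM without the mitochondrially encoded genes alone were chosen after the data were seen. In this part counts of genes are given in the order full-length against eGFP, dMTS against eGFP, and full-length against dMTS, beside 1, 68 and 0 as reported. Without a filter they were 7, 13 and 7, and with a mean of at least 5 TPM 2, 39 and 1. Rescaling gave 4, 1240 and 1, and recomputing TPM without OGDHL and the mitochondrially encoded genes gave 0, 1279 and 1. OGDHL was left out there, and RPPH1, CDKN1A and LINC00161, called for full-length after rescaling, were not called either (adjusted p 0.129, 0.129 and 0.134). Rescaled with OGDHL not among the genes adjusted over, the counts were 0, 1239 and 1, with an adjusted p of 0.0568 for each of the 3. Recomputing TPM without the mitochondrially encoded genes but with OGDHL gave 1, 1284 and 1, with an adjusted p of 0.0972, 0.0972 and 0.120 for the 3. Their log2 fold changes were 0.84 (SE 0.09), -0.35 (SE 0.04) and -0.38 (SE 0.05) there, and 0.74 (SE 0.08), -0.37 (SE 0.04) and -0.39 (SE 0.04) rescaled. That setting is not rescaled and tests 17434 genes in place of 13231, so the lost calls there cannot be put down to 1 change. Voom gave 6, 1789 and 9, and voom rescaled 5, 2154 and 14. Array weights on rescaled libraries gave 5680, 2783 and 349, but their fit did not converge and gave eGFP replicate 2 a weight of 22.1 against 0.291 for the lowest, so these counts rest on a failed fit. The replicate block left 13 of the 68 genes. Rescaling with the block gave 1, 99 and 0, against 4, 1240 and 1 rescaled without it, and called 27 of the 68. A log2 fold minimum of 1 left 4. Leaving out each library in turn gave 1 to 2, 3 to 467 and 0 to 58 genes, and after rescaling 1 to 13, 60 to 2360 and 0 to 911. Genes called for both forms were 4 rescaled and 1 to 2 with a library left out, beside 1 as reported. Of the 68 genes, 6 were called without a filter, 65 of the 67 tested by voom, 3 without eGFP replicate 2, 38 without dMTS replicate 2 and all 68 without dMTS replicate 1. Lists called were 5, 9 and 9 as reported, and 0, 0 and 0 both with an estimated correlation and with fry, as deposited. After rescaling they were 9, 11 and 10 with camera, 0, 0 and 0 with an estimated correlation and 2, 11 and 7 with fry. For full-length against eGFP they were 9 rescaled without dMTS replicate 2, and 3 to 6 with a library left out. The direction of the mitochondrially encoded mRNAs, coded 1 for higher and -1 for lower, turned to 1 for dMTS against eGFP and to -1 for full-length against dMTS without dMTS replicate 2, as deposited and rescaled. Apart from the left-out genes, the cause was not tested for these settings except as described under other observations. Within 1.5 times the reported counts were a pseudocount of 0.1 (62 for dMTS) or 5 (68), the 6 compared libraries alone (46), and a robust eBayes (69). Among fold changes of named genes under all alternatives, 4252 kept their side of the threshold, 405 passed it newly, 68 no longer passed it and none that was called turned. These numbers include the array weights, whose fit failed. That fit gave 42, 61 and 16 of those that passed newly, in the order of comparisons above, and 1 of those lost, for dMTS against eGFP. Among list directions 858 kept their side, 23 passed newly, 60 no longer passed and 4 turned. The 4252 and 858 can include changes of direction where no call was made before or after. The androgen-responsive list, for full-length against eGFP after rescaling, is such a case. The replicate numbers do not pair the samples: residuals of the same number correlated across genes at -0.44 to 0.11 over 9 pairs, of which 1 was over 0.1. In simulated data with 3 libraries per group, differences of 0.5 on the log2 scale were recovered in 46.3% of cases for full-length against eGFP as deposited, so changes of that size can be missed.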

Other observations

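Of the tests in this part, those of dMTS replicate 2 alone, of the amount of OGDHL transcript, of RNAs without a poly(A) tail, of cells in S phase, of the divided eGFP libraries and of the regrouped covariance were chosen after the result was seen, as were the added gene lists and the genes singled out here. Most replication-dependent histone genes, whose mRNAs mostly end without a poly(A) tail, lay lower with dMTS than with eGFP. Of 36 tested, 31 lay lower after rescaling and 13 were called lower, 1 as deposited, with a median log2 fold change of -0.31 (-0.25 as deposited). Among all 13231 genes tested, 801 were called lower after rescaling and 61 as deposited. No list test is given for the histone genes. H2BC21 fell from a mean of 139 to 95.2 TPM (n = 3 each; rescaled -0.61, SE 0.04, limma adjusted p = 0.000932; 0.0523 as deposited). With full-length OGDHL 28 of the 36 lay lower than with eGFP and none was called by limma, as deposited or rescaled.

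Targets of BMP signalling lay lower with dMTS than with eGFP, in a list written after ID1 and ID3 had been seen. After rescaling 11 of 11 lay lower (camera p = 3.28e-06, and p = 0.0325 with an estimated correlation), and as deposited 10 of 11 (camera p = 7.10e-07, and p = 0.0987 with an estimated correlation). ID2 fell from 13.8 ± 1.03 to 8.89 ± 1.17 TPM (SD, n = 3; log2 fold change -0.59, SE 0.10, limma adjusted p = 0.0443), beside ID1 and ID3. SMAD9 was called lower after rescaling (-0.32, adjusted p = 0.0205; 0.265 as deposited). DUSP4, another MAPK phosphatase, went the other way from DUSP2 and was called higher after rescaling (0.49, adjusted p = 0.00604; 0.0643 as deposited).

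The first pattern is the rise from 68 to 1240 genes for dMTS against eGFP after rescaling. Recomputing TPM without OGDHL and the mitochondrially encoded genes gave 1279 genes, 980 of them among the 1240. That setting tested 17437 genes in place of 13231, so its count cannot be put down to 1 change. The share of TPM that the left-out genes take in each library is therefore only a candidate cause of the low count as deposited. How far dMTS replicate 2 alone accounts for it stays open: without that library the rescaled count was 2.07 times the deposited one (176 against 85), while the ratio was 18.2 with all libraries and 5.05 to 139.5 without each of the others. Whether the mitochondrial share reflects the cells or the RNA preparation stays open.

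The second pattern is the smaller fold changes of full-length than of dMTS OGDHL, with a slope of full-length on dMTS values, corrected for noise and the shared controls, of 0.449 (0.30 without dMTS replicate 1 to 0.916 without dMTS replicate 3). The same correction gave a full-length variance of 0.00270, and of -0.000818 without full-length replicate 1. A variance cannot be negative, so the slope is only a rough value. Mean OGDHL was 218 TPM with full-length and 125 TPM with dMTS, so a lower mean amount of transcript does not account for the smaller full-length values. As deposited, though, full-length replicate 2 (165 TPM) lay below dMTS replicate 2 (175 TPM), and protein was not measured. Adding the mitochondrial share of each library to the model left a median of 0.925 of the dMTS fold changes, with 852 of 1239 genes still called. Only genes called without the share, in libraries already rescaled, were compared, and neither the full-length values nor the slope were compared this way. The test therefore cannot decide whether that share makes the full-length values smaller. The covariance of both sets of fold changes was 0.0129 after rescaling. With the eGFP libraries divided between the comparisons it was 0.00598 to 0.0105 over 6 divisions, and 0.00305 to 0.0149 with 1 library left out in turn. A library counted in both comparisons is therefore not its only source. A common response is not established, since what all eGFP libraries have in common stays in every division. The covariance exceeded the highest of 100 simulations, 0.00670, and that of 20 without each library in turn. The simulated genes varied independently, so this bound does not cover genes that vary together. Of all 840 regroupings of the real libraries, 49 gave a corrected covariance as large (5.83%, the real one of 0.00852 among them, highest other 0.0189). The regroupings keep the correlation between genes, and the real one did not stand out among them, so chance is not excluded. The real groups with dMTS as the common group are only 1 of the 840. Regroupings that keep the real groups in part carry their differences too, so the share is not an exact p. A location-dependent action of OGDHL, the difference the design names, stays open. The forms were compared directly, with 9 lists past camera as deposited but none with an estimated correlation, and 0 genes called as deposited and 1 rescaled (58 and 911 without dMTS replicate 1). Location as the cause of those differences is untested, since no library separates it from anything else in which the cells with each form differ.

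The third pattern is the histone transcripts. Reads exchanged between near-identical copies do not account for it, since the summed reads of all 58 histone genes were lower too (log2 ratio -0.453; 23544 to 24994 rescaled reads in dMTS libraries and 32590 to 33676 with eGFP). A lower yield of RNAs without a poly(A) tail stays possible: 41 other such RNAs had a rescaled median of -0.0400 (95% interval -0.12 to 0.04), with 24 lower, 1 called lower and 2 higher, and 0.00 as deposited, with 20 lower, 1 called lower and none higher. No histone gene was called higher. These values go against an equal loss of all such RNAs, but members that go both ways do not decide on a loss that differs between them. Fewer cells in S phase cannot be told apart either, since the cell cycle list had a median of 0.0418 with a camera adjusted p = 0.0355 but an adjusted p = 0.493 with an estimated correlation. That list also holds genes of other phases.

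As hypotheses, lower MAPK output and lower BMP signalling may go with the fall of SPRY4 and DUSP2 and of ID1 and ID3. The lists were written after those genes had been seen and leave them out. The MAPK list had a rescaled median of -0.12, with 8 of 10 lower, 2 called lower and 1 higher (camera p = 0.0314, and p = 0.0657 with an estimated correlation), which is weak. As deposited its median was -0.09, with 7 of 10 lower and none called (camera p = 0.0411, and p = 0.438 with an estimated correlation). The BMP list had a rescaled median of -0.18, with 6 of its 11 genes called lower, and -0.13 as deposited, with 1 called lower, which is in line with lower BMP signalling with dMTS but comes from the data that prompted it.

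For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For full-length against eGFP 1 split, the real one, gave as many genes as deposited (1, highest other 0), rescaled (4, highest other 0) and as lists (5, highest other 3). For dMTS against eGFP 1 split gave as many genes as deposited (68, highest other 7) and rescaled (1240, highest other 0), and 2 gave as many lists (9, highest other 9). For full-length against dMTS all 10 gave as many genes as deposited (0, highest other 4), 3 rescaled (1, highest other 3) and 2 as many lists (9, highest other 9), so these 6 libraries also differ along lines other than the labels; a real count of 0 is matched by every split and says nothing. Among 100 splits of the 9 libraries, 6 gave as many genes called for both forms as deposited (1, highest other 2), and after rescaling 1 did (4, highest other 1). Neither share decides, because both counts rest on OGDHL, which was introduced and so follows the labels by design. With OGDHL out of the count and of the adjustment the real count was 0 both ways, which every split must match, so chance is not excluded for genes called for both forms. For full-length against both other groups the real count was 0 (highest other 1), which all 100 of 100 splits must match, so this test says nothing.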
